A study of Homo sapiens with 15 samples.

How the data were processed

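The deposited table held raw counts of reads per gene for 60617 Ensembl gene identifiers in 15 libraries, as the authors deposited it, and every library was used. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.4, aligned to GRCh38 with STAR 2.5.4b and counted with HTSeq, for which the notes give no version. The settings, the strand handling and the annotation release behind the counts were not stated there. Symbols came from a reference table of gene names, which gave a symbol for 60357 identifiers. The 260 identifiers without one held 0.0387% of all reads. Positions came from GENCODE 29 on GRCh38, which held 58444 of the identifiers, so the coordinates given for genes may differ slightly from those used for counting.

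Groups were taken from the sample titles. The treatment tag of every sample reads DMSO, also for those titled decitabine or combination, and the titles were followed because they match the column names of the table. The titles name the lines C4-2 and C4-2R, where the design text speaks of C4-2B and C4-2B-MDVR, and the names of the titles are used throughout. The design text gives the combination as decitabine plus enzalutamide. Its doses are not in the labels, so they are not given here. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between samples.

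Genes were kept by the edgeR filter on counts per group (filterByExpr with a minimum count of 10), which left 17681 genes for testing. Libraries were scaled by TMM, and a negative binomial quasi-likelihood model with robust dispersion was fitted with edgeR 4.0.16 to all 15 libraries at once, with 1 mean per group and 10 residual degrees of freedom (4 in a fit of only 1 pair of groups). Each of the 5 contrasts was tested two-sided with glmQLFTest, and p-values were adjusted by the Benjamini-Hochberg method over the 17681 genes of that contrast. A gene was called changed at an adjusted p under 0.05. Log2 fold changes are given with an approximate standard error (SE). It was derived by dividing the absolute log2 fold change by the square root of the F statistic of the test. It was not estimated separately, and is only a rough guide for genes near 0 reads in a group. Levels are given as CPM (read counts scaled to a common library size), as the mean ± standard deviation (SD) of the 3 libraries of a group. Where all 3 libraries of a group had 0 reads, the fold is a lower bound computed against a floor of 3 counts over the group, which at the TMM-scaled library sizes behind CPM is 0.0432 to 0.0477 CPM depending on the group. Where a group had 1 to 3 reads, the ratio of CPM is given with its 95% counting interval in place of a fitted value. These intervals and floors cover counting error only.

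The genes named in the text follow a fixed rule. In each comparison it takes the 8 genes with the largest change in each direction among those that were called, whose libraries did not overlap between the groups, and whose mean reached 5 CPM in at least 1 of the groups. It adds up to 4 called members of each gene list with the largest changes, the 8 genes with the largest reversal in each direction, and a fixed set that held DNMT1, DNMT3A, DNMT3B and KLK3 in every comparison. Genes outside this rule are said to have been chosen after their values were seen.

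Of the 27 gene lists 1 is not used here, but its tests stay in the adjustment and in the counts of lists. The others were DNA methylation machinery, androgen-responsive genes, nuclear receptors and steroid enzymes, cancer-testis and germline genes, interferon-stimulated and RNA-sensing genes, antigen presentation, genes silenced by promoter methylation in prostate cancer, neuroendocrine, proliferation, mesenchymal, luminal and basal epithelial, Wnt pathway, sterol and fatty acid synthesis, unfolded protein and amino acid stress response, decitabine uptake and metabolism, imprinted, endogenous retroviral, and immune checkpoint and chemokine genes. The rest were markers of fibroblasts, leukocytes, endothelial cells, and HeLa and other carcinoma lines, and signs of RNA quality (mitochondrial transcripts, immediate early genes, unpolyadenylated histone genes). Each list was tested two-sided against all other genes with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and adjusted over the 135 list tests. The same test with a correlation estimated from the data, and fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, were run as alternatives. The comparisons, the model, thresholds, lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those that the closing section names as chosen later.

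The alternatives for each result were scaling by DESeq2-type size factors (RLE), the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, a stricter filter (1 CPM in at least 3 libraries), a fit on only the 6 libraries compared, the replicate number as a block, an adjusted p under 0.01, a test against a minimum log2 fold change of 0.5 (glmTreat), and leaving out each library in turn. All ran in R 4.3.3. To see whether replicate numbers pair the libraries, residuals of libraries with the same number were correlated across genes, which are not independent replicates. Between decitabine and the combination these correlations were 0.26, 0.15 and 0.48 for replicates 1, 2 and 3, against -0.15 to 0.11 in the other 4 comparisons, and for replicate 2 the highest correlation with another number was 0.23. LNCaP and C4-2, which are not compared with each other but both enter the reversal, had 0.21, 0.5 and 0.3. Values with the replicate block are therefore printed for the list tests and counts of the combination against decitabine, and for single genes where the block changed the call.

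The procedure was tried on counts simulated from these libraries. For true changes of 1.5, 2 and 4-fold it recovered 59.7%, 83.6% and 97% of changed genes for C4-2R against LNCaP, 65.7%, 79.1% and 92.4% against C4-2, 58.2%, 88.1% and 98.5% for decitabine against DMSO, 64.2%, 79.1% and 95.5% for the combination against DMSO, and 47.8%, 77.6% and 98.5% for the combination against decitabine. Of the genes simulated without a change it called 6, 10, 13, 2 and 7 in these comparisons, in the same order, among 17681 genes run. In each comparison only 67, 67 and 66 genes were changed by 1.5, 2 and 4-fold, while 1512 to 10280 genes were called in the data. The adjustment depends on how many genes change, so these rates and false calls need not hold for the data. Recovery was not split by read level, so it is not known for genes with low counts. For the overlap between comparisons that share the C4-2R DMSO libraries, 20 data sets were simulated without a treatment effect. They give the covariance that shared controls alone produce, but call hardly any gene with treatment and so bound no overlap between real effects.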

Results

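RNA was sequenced from cultured human prostate cancer cells in 15 libraries that form 5 groups of 3 replicates. LNCaP is an androgen-responsive line from a lymph node metastasis, C4-2 is a castration-resistant line derived from it, and C4-2R is the line that the design describes as resistant to enzalutamide, an antiandrogen. The groups were LNCaP, C4-2 and C4-2R cells in DMSO, the solvent control, C4-2R cells with 500 nM decitabine, and C4-2R cells with the combination of decitabine and enzalutamide. Decitabine is a cytidine analogue that traps DNA methyltransferases on DNA and so lowers methylation in dividing cells. Treatment lasted 72 h with the medium changed every 24 h. Total counts per library were 18.44 to 21.84 M for LNCaP, 21.71 to 24.05 M for C4-2, 20.88 to 24.98 M for C4-2R in DMSO, 20.2 to 23.79 M with decitabine and 21.12 to 24.76 M with the combination. Of the 60617 genes in the table, 30270 had 0 reads in all libraries and 17681 were tested. Genes above 1 CPM numbered 12932 ± 102 (SD, n = 3) in C4-2R DMSO, 14006 ± 167 with decitabine, 14214 ± 69.8 with the combination, 13445 ± 303 in LNCaP and 13743 ± 411 in C4-2. Mitochondrial transcripts took 4.91% ± 0.568 of counts in LNCaP, 11% ± 2.54 in C4-2, 1.96% ± 0.215 in C4-2R DMSO, 3.14% ± 0.63 with decitabine and 3.58% ± 0.778 with the combination. In all comparisons n = 3 per group, and unless stated the 3 libraries of one group lay wholly above or below the 3 of the other for each gene said to rise or fall by the rule for the largest changes.

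**Figure D1:**
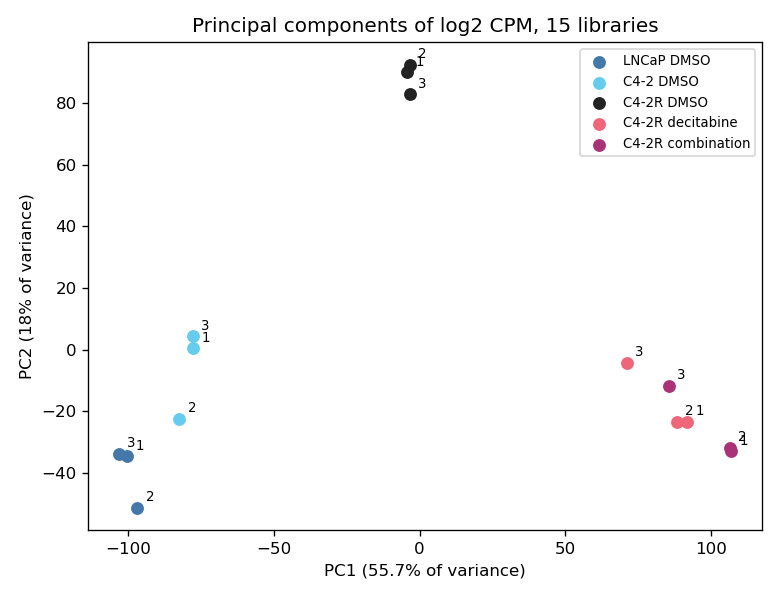
Each point is 1 of the 15 libraries, labelled with its replicate number, on the first 2 principal components of log2 CPM (PC1 55.7% and PC2 18% of the variance). The groups lie apart, and replicate 3 of both treated groups lies nearer to C4-2R DMSO than replicates 1 and 2.

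The series asks about DNMT3B and the other DNA methyltransferases in enzalutamide resistance, and the transcripts of these enzymes moved in different ways. DNMT1, which copies methylation to new DNA strands (ENSG00000130816, GRCh38 chromosome 19, 10133345–10231286), stood at 312 ± 23.8 CPM in C4-2R DMSO against 171 ± 13.5 in LNCaP and 205 ± 17.3 in C4-2, and fell to 167 ± 8.9 with decitabine and 180 ± 14.5 with the combination. The log2 fold changes were 0.87 ± 0.09 (SE) against LNCaP (adjusted p = 4.63e-07), 0.61 ± 0.09 against C4-2 (2.95e-05), -0.9 ± 0.09 with decitabine (1.04e-06) and -0.8 ± 0.09 with the combination (2.81e-06). DNMT3B, which sets new methylation marks (ENSG00000088305, chromosome 20, 32762385–32809356), was higher in C4-2R than in LNCaP by 0.96 ± 0.17 (adjusted p = 0.000121), at 29.2 ± 1.41 against 14.9 ± 2.45 CPM, and did not pass the test against C4-2, which had 33.2 ± 4.62 CPM (-0.19, adjusted p = 0.344). With decitabine it stood at 28.9 ± 7.79 CPM (adjusted p = 0.959). With the combination it rose by 0.41 ± 0.16 (adjusted p = 0.0469), a call that was lost when any single library of the 6 compared was left out (adjusted p 0.0769 to 0.282) and also without the filter or with the replicate block. The difference of the combination from decitabine did not pass for DNMT3B (0.42, adjusted p = 0.137), though it did without decitabine replicate 3 (0.63, adjusted p = 0.0216). DNMT3A, the other enzyme of new methylation (ENSG00000119772, chromosome 2, 25227855–25342590), was lower in C4-2R than in C4-2 by 0.67 ± 0.15 (adjusted p = 0.00111) and than in LNCaP by 0.52 ± 0.15 (0.00739, but -0.36 and 0.062 without LNCaP replicate 2), and did not pass with either treatment (adjusted p = 0.83 and 0.092).

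**Figure D2:**
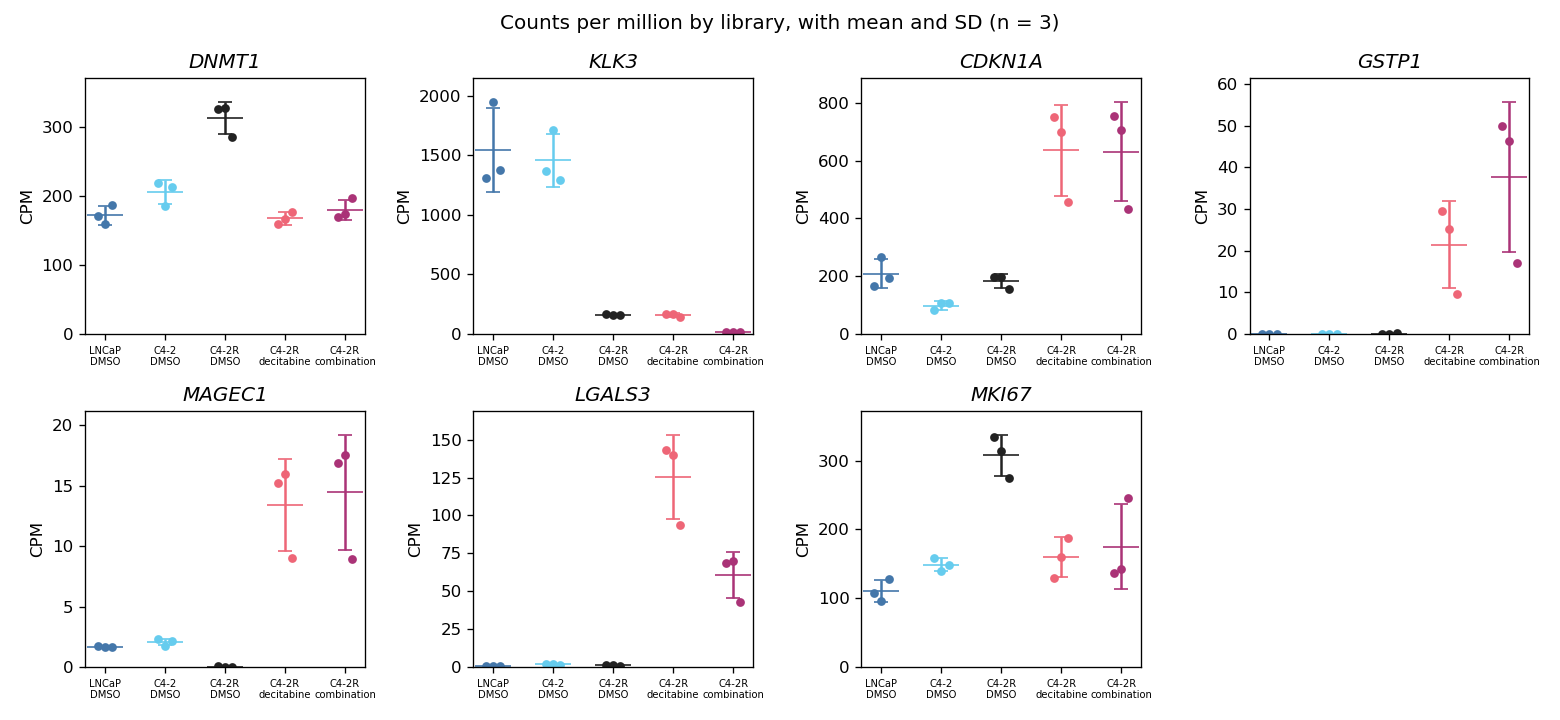
CPM of 7 genes (DNMT1, KLK3, CDKN1A, GSTP1, MAGEC1, LGALS3, MKI67) in each library of the 5 groups, with the mean and SD of 3 libraries per group. KLK3 falls in 2 steps, from 1550 and 1460 CPM in LNCaP and C4-2 to 164 in C4-2R DMSO and to 16.6 with the combination, while MAGEC1 rises from near 0 to 13.4 CPM with decitabine.

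C4-2R was compared with LNCaP, a line sensitive to enzalutamide, to find genes that change in the resistant line. C4-2R carried far less mRNA of genes that androgens induce. KLK3, which encodes prostate-specific antigen (ENSG00000142515, chromosome 19, 50854915–50860764), fell by a log2 fold change of 3.24 ± 0.15 (164 ± 4.22 against 1550 ± 348 CPM, adjusted p = 6.56e-12), and so did the prostaglandin-degrading enzyme gene HPGD (-6.36 ± 0.35) and the protease gene ADAMTS1 (-4.59 ± 0.15). Of 28 tested androgen-responsive genes 23 fell and 1 rose (24 and 1 adjusted over the list alone). At a median of -1.52, the list test gave an adjusted p = 1.5e-08 and adjusted p = 0.44 with an estimated correlation. Genes of cell division were higher, with 31 of 40 proliferation genes raised and 1 lowered (31 and 1 adjusted over the list alone). The median was 0.69, and the list test gave an adjusted p = 1.9e-07 and adjusted p = 0.65 with an estimated correlation. Among them were the anaphase activator CDC20 (1.88 ± 0.18, 354 against 96.5 CPM), the mitotic kinase PLK1 (1.82 ± 0.18) and the proliferation marker MKI67 (1.48 ± 0.2, 308 ± 30 against 110 ± 16.5 CPM).

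Immune checkpoint and chemokine genes, and genes of sterol synthesis and stress, also differed between C4-2R and LNCaP. Interferon-stimulated and RNA-sensing genes (8 higher and 15 lower of 35) did not pass the list test (adjusted p = 0.47). Antigen presentation genes (2 higher and 6 lower of 15) did not pass it either (adjusted p = 0.59). Of 9 immune checkpoint and chemokine genes 8 fell (8 adjusted over the list alone). For these genes the median was -2.82, and the list test gave an adjusted p = 0.00029 and adjusted p = 0.42 with an estimated correlation. The neutrophil attractant CXCL8 had a ratio of 1550 in favour of LNCaP (95% counting interval 278 to 61200), CCL20 one of 907 (163 to 35800), and the monocyte attractant CCL2 was at least 91.3-fold lower in C4-2R. Of 26 genes of sterol and fatty acid synthesis 14 rose and 2 fell (14 and 2 adjusted over the list alone). Their median was 0.44 with an adjusted p = 0.024, adjusted p = 0.64 with an estimated correlation, and 0.06 without C4-2R DMSO replicate 3. Among them was the sterol sensor INSIG1 (1.54 ± 0.14, 352 against 121 CPM). Of 23 genes of the unfolded protein and amino acid stress response 13 rose (13 adjusted over the list alone). Their median was 0.44 with an adjusted p = 0.019, adjusted p = 0.65 with an estimated correlation, and 0.1 without C4-2R DMSO replicate 3. The endoplasmic reticulum chaperone genes SDF2L1 and HSP90B1 rose by 1.47 ± 0.12 (189 against 68.2 CPM) and 0.77 ± 0.09. All 13 mitochondrial transcripts, a sign of RNA quality, were lower in C4-2R beside these groups (13 adjusted over the list alone). With a median of -1.26, the list test gave an adjusted p = 4e-05 and adjusted p = 0.64 with an estimated correlation, with MT-ND4 at -1.58 ± 0.22.

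The largest increases over LNCaP included several genes normally active in germ cells. CT83 was at least 176-fold higher (8.37 ± 1.17 CPM against 0 reads), PASD1 rose by 8.7 ± 0.2 (48.7 against 0.114 CPM), CTAG2 by 8.49 ± 0.16 (110 against 0.3 CPM) and PAGE1 by 7.37 ± 0.14 (295 against 1.77 CPM). CT45A10 had a ratio of 447 (124 to 3690), which is uncertain because reads of that near-identical family cannot be assigned to 1 member with ease. As a list, cancer-testis genes did not pass (10 rose and 5 fell of 37, also adjusted over the list alone, median 0.09, adjusted p = 0.12). The transcription factor gene GATA5 was at least 119-fold higher, SLFN13 had a ratio of 864 (239 to 7140), HOXD13 one of 481 (86.3 to 19000), and the Wnt antagonist SFRP1, often silenced in prostate cancer, rose by 7.16 ± 0.25 (25.7 against 0.173 CPM). On the lower side stood Y-linked genes, of which EIF1AY was at least 1380-fold lower and DDX3Y fell by 10.21 ± 0.53. The metallothionein gene MT1G, another gene often silenced in prostate cancer, had a ratio of 1600 in favour of LNCaP (288 to 63300), the mesenchymal transcription factor gene TWIST1 fell by 9.91 ± 0.48 (0.0605 against 65.1 CPM), and UGT2B17, which glucuronidates androgens, fell by 6.46 ± 0.3 (3.58 against 316 CPM). In total 4996 genes were higher and 5084 lower in C4-2R (57% of those tested), 1681 and 2661 of them by at least 2-fold, and the libraries did not overlap for 64% of tested genes where chance gives 10%.

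C4-2R was compared with C4-2, the other enzalutamide-sensitive line of the design, for the same question. Androgen-responsive genes were lower and proliferation genes higher, as in the comparison with LNCaP. KLK3 fell by 3.15 ± 0.15 (adjusted p = 1.96e-11), ADAMTS1 by 4.85 ± 0.15 and the cold-sensing channel gene TRPM8 by 3.38 ± 0.22. Of 28 androgen-responsive genes 23 fell and 1 rose (24 and 1 adjusted over the list alone). At a median of -1.35, the list test gave an adjusted p = 2.3e-09 and adjusted p = 0.44 with an estimated correlation. Of 40 proliferation genes 30 rose (30 adjusted over the list alone). The median was 0.69, and the list test gave an adjusted p = 1.2e-07 and adjusted p = 0.65 with an estimated correlation. The replication helicase subunit gene MCM2 rose by 1.41 ± 0.14 (431 against 163 CPM) and PLK1 by 1.24 ± 0.17. All 13 mitochondrial transcripts were lower here too (13 adjusted over the list alone, median -2.52, adjusted p = 1.2e-09, adjusted p = 0.6 with an estimated correlation), with MT-ND4 at -2.71 ± 0.23.

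Among the genes furthest below C4-2 were the transcription factor gene SP8 (at least 222-fold lower, 0 reads against 10.3 ± 1.47 CPM), the retinaldehyde dehydrogenase gene ALDH1A1, a marker of stem-like cells (-9.01 ± 0.33, 0.221 against 115 CPM), the adhesion receptor gene ADGRL2 (-8.65 ± 0.29, 0.322 against 127 CPM), the engulfment adaptor gene GULP1 (-8.12 ± 0.5) and TTC29 (ratio 334, 92.4 to 2760). Among those furthest above it were the long non-coding RNA LINC01019 (ratio 324, 89.6 to 2670), PASD1 (7.19 ± 0.17), the immune receptor gene CD40 (6.4 ± 0.36, 5.49 against 0.0588 CPM), and the zinc finger gene ZNF516 (6.18 ± 0.23, 32.8 against 0.443 CPM) with its divergent transcript ZNF516-DT (ratio 312, 86.4 to 2580). Of 37 cancer-testis genes 9 rose and 4 fell (8 and 4 adjusted over the list alone, median 0.32 and 0.2 with genes at 0 reads at their bound, adjusted p = 0.22). CTAG2 rose by 4.61 ± 0.11 (110 against 4.51 CPM), while MAGEC1 had a ratio of 44.9 in favour of C4-2 (15.4 to 218). Immune checkpoint and chemokine genes did not pass as a list (1 rose and 6 fell of 9, also adjusted over the list alone, median -1.86 and -1.67 with genes at 0 reads at their bound, adjusted p = 0.054, but 0.048 with the replicate block and 3.4e-05 with fry). In total 4992 genes were higher and 5288 lower (58.1%), 1167 and 3116 of them by at least 2-fold, and 63.3% of tested genes did not overlap between the groups.

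Decitabine was set against DMSO in C4-2R to see which genes respond to it in resistant cells. Germline genes that were near 0 reads in DMSO rose together. Of 37 cancer-testis and germline genes 25 rose and 1 fell (25 and 2 adjusted over the list alone). For these genes the median was 5.26, and the list test gave an adjusted p = 5.6e-08 and adjusted p = 0.6 with an estimated correlation. The list has 51 members, and those silent in C4-2R DMSO were tested only if another group expressed them. The filter thus partly fixes the counts, the median and the list test. The same holds for other gene sets with members silent in DMSO, and with the combination. PAGE2 was at least 121-fold and LY6K at least 95.5-fold higher, PAGE5 had a ratio of 816 (146 to 32200), MAGEB2 one of 587 (162 to 4840) and MAGEC1 one of 289 (99 to 1400), at 13.4 ± 3.79 CPM. CTAG2, chosen after its values were seen and already abundant in these cells, had a log2 fold change of -0.14 ± 0.09 (adjusted p = 0.2). Genes silenced by promoter methylation in prostate cancer also rose, 12 of 22 with 2 lower (12 and 2 adjusted over the list alone). With a median of 0.98, the list test gave an adjusted p = 0.035 and adjusted p = 0.64 with an estimated correlation. They included the glutathione transferase GSTP1, whose promoter is methylated in most prostate cancers (7.77 ± 0.8, 21.4 ± 10.5 against 0.0955 CPM), the annexin ANXA2 (7.69 ± 0.65, 36.1 against 0.165 CPM) and, chosen after its values were seen, the galectin LGALS3 (6.92 ± 0.26, 126 ± 27.9 against 1.03 CPM). S100A6 was at least 29.2-fold higher.

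Proliferation genes fell with decitabine. Of 40 proliferation genes 36 fell (36 adjusted over the list alone). At a median of -0.76, the list test gave an adjusted p = 1.8e-13 and adjusted p = 0.62 with an estimated correlation. Among them were thymidylate synthase TYMS (-1.11 ± 0.12, 34.3 against 73.8 CPM), the ribonucleotide reductase subunit RRM2 (-1.09 ± 0.14, 146 against 312 CPM) and the replication helicase subunit MCM7 (-1.1 ± 0.15). The cell cycle inhibitor CDKN1A rose by 1.79 ± 0.24 (636 ± 158 against 184 ± 23.3 CPM), the stress cytokine GDF15 by 3.63 ± 0.83 (212 against 17.2 CPM) and the mitophagy gene SPATA18 by 1.46 ± 0.25. Of 35 interferon-stimulated and RNA-sensing genes 17 rose and 3 fell (17 and 3 adjusted over the list alone). For these genes the median was 0.56, and the list test gave an adjusted p = 0.02 and adjusted p = 0.64 with an estimated correlation. IFI27 rose by 2.71 ± 0.42 (3.33 against 0.498 CPM), MX2 by 2.2 ± 0.45 and the exonuclease gene ISG20 by 1.92 ± 0.23, while 8 other members, IFIT1 and OAS2 among them, were listed at 0 in all libraries. Of 15 antigen presentation genes 7 rose (7 adjusted over the list alone), and the list did not pass (adjusted p = 0.081, but 0.04 without DMSO replicate 1 and 0.044 without decitabine replicate 3). The endogenous retroviral gene ERVH48-1 rose by 6.41 ± 0.5 (7.03 against 0.0744 CPM) and the imprinted RNA H19 by 3.54 ± 0.27 (9.99 against 0.86 CPM).

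Androgen-responsive genes as a list did not pass with decitabine alone (6 rose and 3 fell of 28, also adjusted over the list alone, median 0.12, adjusted p = 0.5). KLK3 had a log2 fold change of -0.04 ± 0.14 (159 ± 15.8 against 164 ± 4.22 CPM, adjusted p = 0.819). The protease gene TMPRSS2 rose by 1.48 ± 0.2 (182 against 65.6 CPM) and HPGD by 1.56 ± 0.43. The largest single falls were the bile salt pump ABCB11 (-3.89 ± 0.48, 1.35 against 19.9 CPM), PHLDA1 (-3.23 ± 0.19, 1.87 against 17.7 CPM), the transcription factor gene MYB (-2.23 ± 0.22, 2.72 against 12.8 CPM) and the kinase gene MAP2K6 (-2.18 ± 0.21). The largest rises were the kinase subunit PIK3CG (at least 189-fold, 8.75 ± 3.69 CPM against 0 reads), the ferritin-like FTHL17 (at least 166-fold), the metallothionein MT1E (at least 148-fold), MAGEA8 (at least 127-fold) and the testis factor gene DMRTB1 (ratio 1310, 235 to 51700). Beside these groups 9 of 13 mitochondrial transcripts were higher (11 adjusted over the list alone). With a median of 0.59, the list test gave an adjusted p = 0.016 and adjusted p = 0.65 with an estimated correlation. This call was lost without DMSO replicate 3 (0.052) or decitabine replicate 1 or 2 (0.055 each) and with fry (0.058), and MT-CO2 rose by 0.69 ± 0.19. All 4 leukocyte markers tested rose too (4 adjusted over the list alone). At a median of 3.09, the list test gave an adjusted p = 0.039 and adjusted p = 0.6 with an estimated correlation. CD14 reached 4.29 ± 1.84 CPM at a ratio of 92.6 (31.7 to 449). The call was lost without DMSO replicate 1 (0.085), 2 (0.091) or 3 (0.091) or decitabine replicate 1 (0.056). The member CSF1R (0.76 ± 0.3, adjusted p = 0.0444) lost its own call without any single library of the 6 (0.0654 to 0.123), with DESeq2 (0.105), without the filter (0.156) and with the replicate block (0.0512). In total 4211 genes rose and 3640 fell (44.4% of those tested), and at least 2-fold 2488 rose and 490 fell. Of the genes that rose 1656 (39.3%) started below 0.5 CPM, and 3292 of all 17681 tested genes lay below it in DMSO. Such a gene was tested only if another group expressed it, so the filter can raise this share. The libraries did not overlap between the groups for 61.2% of tested genes.

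**Figure D3:**
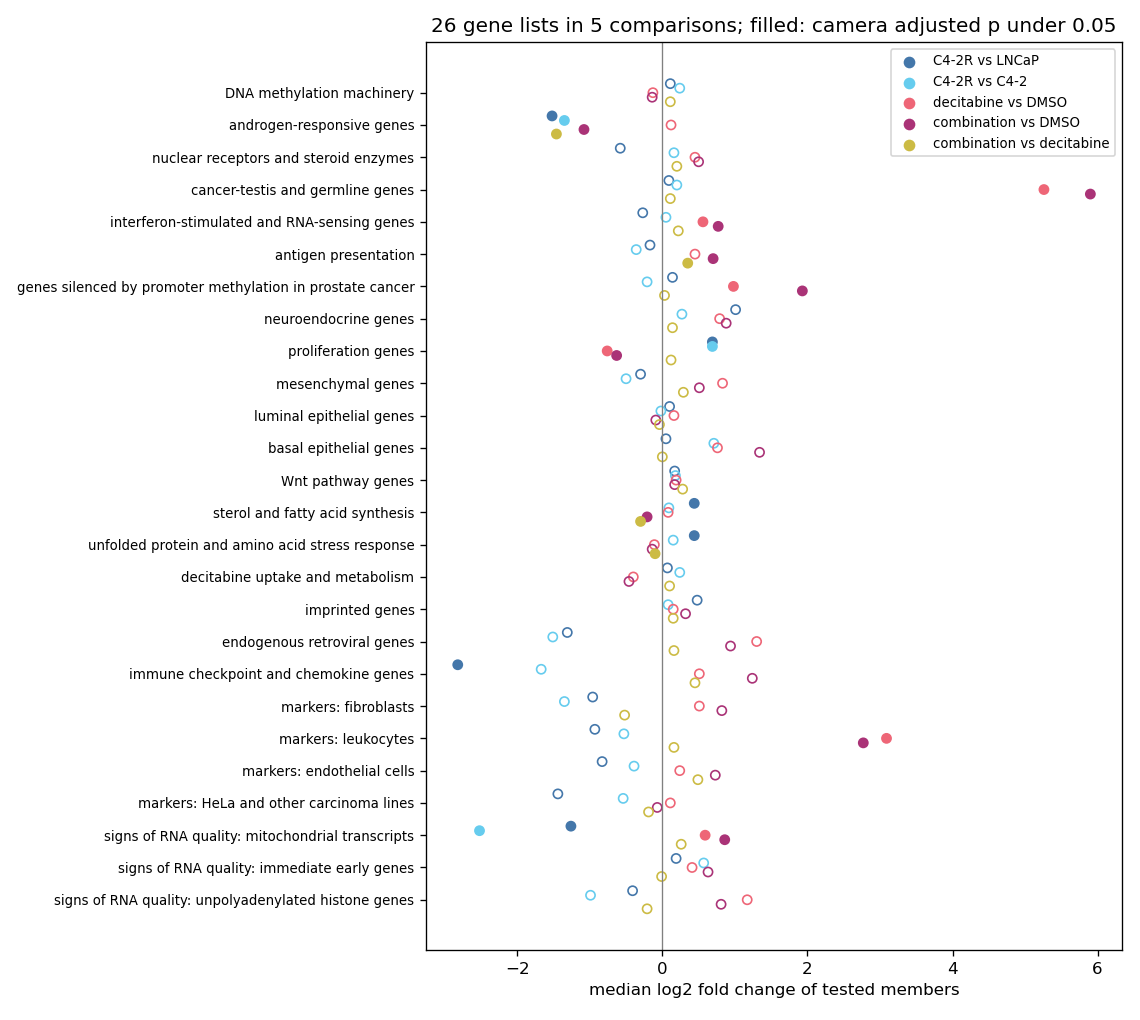
Median log2 fold change of the tested members of 26 gene lists in the 5 comparisons, with genes at 0 reads set at their bound and filled symbols for an adjusted p under 0.05 in the list test. Androgen-responsive genes lie low in every comparison except decitabine against DMSO, and proliferation genes lie above 0 in the resistant line and below 0 with both treatments.

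The combination was set against DMSO in C4-2R to see which genes respond to decitabine with enzalutamide. KLK3 fell by 3.3 ± 0.15 to 16.6 ± 1.1 CPM (adjusted p = 8.38e-11). The related kallikrein gene KLK2 fell as well (-4.05 ± 0.24, 9.5 against 157 CPM), and HPGD was at least 7.54-fold lower. Of 28 androgen-responsive genes 22 fell and 2 rose (22 and 2 adjusted over the list alone). The median was -1.08, and the list test gave an adjusted p = 7.3e-09 and adjusted p = 0.44 with an estimated correlation. The glycosyltransferase gene ST6GALNAC1 fell by 4.34 ± 0.2 (11.6 against 235 CPM). The transporter gene SLC45A3, which codes for prostein (-3.89 ± 0.19, 19.2 against 284 CPM), and the nicotinic receptor gene CHRNA2 (-5.1 ± 0.56) fell too.

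The lists called with decitabine alone were called with the combination as well. Of 37 cancer-testis genes 25 rose and 1 fell (26 and 2 adjusted over the list alone). For these genes the median was 5.9, and the list test gave an adjusted p = 1.2e-07 and adjusted p = 0.61 with an estimated correlation. PAGE2 was at least 144-fold and LY6K at least 83.5-fold higher, and PAGE5 had a ratio of 1030 (184 to 40500). Of 22 genes silenced by promoter methylation in prostate cancer 13 rose and 3 fell (15 and 3 adjusted over the list alone). With a median of 1.93, the list test gave an adjusted p = 0.013 and adjusted p = 0.64 with an estimated correlation. GSTP1 rose by 8.58 ± 0.79 (37.7 ± 18 CPM) and the adhesion receptor CD44 by 8.06 ± 0.8. Of 40 proliferation genes 35 fell (37 adjusted over the list alone). At a median of -0.63, the list test gave an adjusted p = 3.2e-10 and adjusted p = 0.64 with an estimated correlation. RRM2 fell by 1.21 ± 0.14. CDKN1A rose by 1.78 ± 0.24 and GDF15 by 3.21 ± 0.82. Of 35 interferon-stimulated and RNA-sensing genes 23 rose and 4 fell (24 and 4 adjusted over the list alone). For these genes the median was 0.77, and the list test gave an adjusted p = 0.0011 and adjusted p = 0.61 with an estimated correlation. IFI27 rose by 3.93 ± 0.41 (7.79 CPM), the antiviral gene OASL by 2.62 ± 0.34 (8.22 against 1.34 CPM) and tetherin, BST2, by 2.53 ± 0.23 (15.5 against 2.67 CPM). Of 15 antigen presentation genes 10 rose (11 adjusted over the list alone). With a median of 0.7, the list test gave an adjusted p = 0.0029 and adjusted p = 0.62 with an estimated correlation. Among them were the immunoproteasome subunits PSMB9 (1.55 ± 0.29, 5.63 against 1.92 CPM), PSMB10 (1.41 ± 0.31) and PSMB8 (1.26 ± 0.25), while the peptide transporter genes TAP1 and TAP2 were listed at 0 in all libraries. Genes of the unfolded protein response did not pass (2 rose and 6 fell of 23, adjusted p = 0.16, but 0.04 without DMSO replicate 1).

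Sterol and fatty acid genes moved down with the combination, 8 of 26 lower and 1 higher (7 and 1 adjusted over the list alone). Their median was -0.21 with an adjusted p = 0.037, adjusted p = 0.64 with an estimated correlation, and 0.076 without DMSO replicate 3. The fatty acid enzyme ACACA fell by 0.57 ± 0.1 and the isoprenoid enzyme FDPS by 0.54 ± 0.07. Beside these groups all 13 mitochondrial transcripts were higher (13 adjusted over the list alone, median 0.86, adjusted p = 0.0011, adjusted p = 0.65 with an estimated correlation). MT-CO1 rose by 0.91 ± 0.21. All 4 leukocyte markers tested rose (4 adjusted over the list alone, median 2.77, adjusted p = 0.048, adjusted p = 0.6 with an estimated correlation). This call was lost without DMSO replicate 1 (0.055), 2 (0.07) or 3 (0.067) or combination replicate 2 (0.054). In total 4657 genes rose and 3839 fell (48.1%), 2849 and 567 of them by at least 2-fold. Of those that rose 1809 (38.8%) started below 0.5 CPM, as did 3292 of all 17681 tested genes, with the same limit from the filter. The libraries did not overlap between the groups for 62.6% of tested genes.

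The combination was also compared with decitabine alone, a comparison that the series does not name. Androgen-responsive genes had the lowest p of all lists, with 22 of 28 lower and 1 higher (23 and 2 adjusted over the list alone). At a median of -1.46, the list test gave an adjusted p = 3.8e-30 and 2e-28 with the replicate block and adjusted p = 0.053 with an estimated correlation. KLK3 was lower by 3.26 ± 0.15 (16.6 ± 1.1 against 159 ± 15.8 CPM, adjusted p = 4.64e-10), KLK2 by 3.55 ± 0.24 (9.5 against 111 CPM), SLC45A3 by 4 ± 0.19 (19.2 against 306 CPM), ST6GALNAC1 by 4.29 ± 0.2 (11.6 against 228 CPM), and HPGD was at least 22.4-fold lower. The androgen-induced zinc finger gene ZBTB16 was at -3.61 ± 0.19. Sterol and fatty acid genes were lower, 8 of 26 with 1 higher (11 and 1 adjusted over the list alone). The median was -0.3, and the list test gave an adjusted p = 2e-06 and 3.5e-06 with the replicate block and adjusted p = 0.44 with an estimated correlation. The cholesterol synthesis gene HMGCS1 was at -0.82 ± 0.17 and ACACA at -0.69 ± 0.1. Higher with the combination were the bile acid enzyme CYP7A1 (6.15 ± 0.51, 5.77 against 0.0754 CPM), the secreted phospholipase PLA2G2A (4.19 ± 0.51, 46.3 ± 11.8 against 2.52 CPM) and the collectin COLEC12 (2.57 ± 0.18, 52.8 against 8.86 CPM).

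Antigen presentation genes were also called against decitabine (3 of 15 higher, 5 adjusted over the list alone). For these genes the median was 0.35, and the list test gave an adjusted p = 0.019 and 0.01 with the replicate block and adjusted p = 0.64 with an estimated correlation. Without combination replicate 2 the call was lost (0.07). Genes of the unfolded protein response were lower (4 of 23, with 8 lower and 1 higher adjusted over the list alone). With a median of -0.1, the list test gave an adjusted p = 0.039 and 0.036 with the replicate block and adjusted p = 0.65 with an estimated correlation. The co-chaperone DNAJB9 was at -0.61 ± 0.14, and the list call was lost without decitabine replicate 3 (0.29) or combination replicate 1 (0.053) or 2 (0.097) and with fry (0.29). With the replicate block 7 lists passed, adding interferon-stimulated genes (0.044, against 0.053 without it), Wnt pathway genes (0.046 against 0.056) and mitochondrial transcripts (0.024 against 0.11). Single libraries decided several list tests here. Interferon-stimulated genes passed without decitabine replicate 1 (0.021) or 2 (0.024) or combination replicate 3 (0.00089), and mitochondrial transcripts without the same libraries (0.017, 0.023 and 0.00046). Wnt pathway genes passed without decitabine replicate 1 (0.018) or combination replicate 1 (0.046) or 3 (0.04), and cancer-testis (0.012) and immune checkpoint and chemokine genes (0.027) without combination replicate 3. Proliferation genes (0.011) and unpolyadenylated histone genes (0.03) passed without decitabine replicate 3. BST2 was higher by 1.06 ± 0.21 (adjusted p = 0.00301) and the RNA sensor TLR3 by 1.2 ± 0.23 (0.00209), while HERC6, also interferon-induced, was lower by 0.94 ± 0.14. LGALS3 was lower by 1.05 ± 0.18 (adjusted p = 0.000854). In total 735 genes were higher and 777 lower (8.55%), 277 and 282 of them by at least 2-fold, against 871 and 875 with the replicate block, and 31.8% of tested genes did not overlap between the groups. The count of higher genes was 372, 359 and 371 without decitabine replicate 1, 2 and 3, and 308 and 305 without combination replicate 1 and 2, and the 4 lists called became 8 and 7 without decitabine replicate 1 and 2, and 2 and 10 without combination replicate 2 and 3.

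The series looked for genes whose change in resistance is reversed by treatment. C4-2R is the only resistant line here, so changes that go with resistance cannot be told apart from other differences between the lines. Of 3339 genes lower in C4-2R than in both other lines, decitabine raised 1014 (30.4%) and the combination 1005 (30.1%). Of 3512 genes higher in C4-2R than in both, decitabine lowered 1334 (38%) and the combination 1260 (35.9%). The balance depended on the size of change asked for, since at least 2-fold in every comparison left 499 raised and 61 lowered by decitabine and 531 and 47 by the combination, and glmTreat gave 388 and 121, and 437 and 91. Independent lists of these sizes would share 795.2, 879.5, 723 and 762.5 genes, in the order raised by decitabine, raised by the combination, lowered by decitabine and lowered by the combination. Further change in the same direction was rarer, with 416 genes lowered further and 415 raised further by decitabine, and 539 and 594 by the combination. Simulated libraries without a treatment effect gave a mean of 0 reversed genes, but hardly any gene is called in them, so this does not show what shared controls add beside real effects. By group, proliferation genes reversed in large part, since 28 were higher in C4-2R than in both lines and 26 of these fell with decitabine and 25 with the combination. Androgen-responsive genes mostly did not reverse, but neither did most genes lower in C4-2R (30.4% rose with decitabine and 30.1% with the combination). Of the 22 androgen-responsive genes lower in C4-2R than in both lines, 5 rose with decitabine and 1 with the combination. The 5 with decitabine are not far from the share of all such genes, and no difference from it was tested. Of 10 interferon-stimulated genes lower in C4-2R than in both, 5 rose with each treatment, while of 6 that were higher in C4-2R than in both 1 fell with each, and all 13 mitochondrial transcripts were lower in C4-2R than in both, with 9 raised by decitabine and 13 by the combination.

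Single reversed genes included MAGEC1, at 1.68 CPM in LNCaP, 2.08 in C4-2, 0.0417 in C4-2R DMSO, 13.4 with decitabine and 14.5 with the combination, and MAGEA8, at 0.655, 0.243, 0, 5.89 and 7.04 CPM in the same order. The zinc finger gene ZNF728 went from 4.75 and 14.3 CPM in LNCaP and C4-2 to 0.126 in C4-2R DMSO and 1.83 with decitabine. In the other direction stood the natriuretic peptide clearance receptor NPR3, at 1.38, 2.25, 18.6, 4.99 and 4.93 CPM, the transcription factor gene WT1, at 0.734, 7.63, 18.8, 7.9 and 7.26 CPM, MYB, at 5.49, 4.27, 12.8, 2.72 and 3.77 CPM, SFRP1, at 0.173, 1.8, 25.7, 11.3 and 11.6 CPM, and the replication factor gene GINS1, at 80.3, 82.2, 173, 71.6 and 79.9 CPM. The comparisons share the C4-2R DMSO libraries, and these are too few to divide between them. The covariance across genes of the C4-2 contrast with the decitabine contrast was -0.242, where shared controls alone gave -0.0373 in simulation, so part of the negative relation can come from the shared libraries (genes are not independent replicates). Both treatments changed many of the same genes, with 3477 raised and 2792 lowered by both where independent lists would share 1109.1 and 790.3, and with 77 and 17 changed in opposite directions. Independence is not the state without an effect for this pair, as both use the same DMSO libraries. Their covariance was 1.09, where shared controls alone gave 0.0377 in simulation (Pearson correlation 0.91 and 0.51), and part of the overlap can come from these libraries.

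The remaining lists did not pass in any of the 5 comparisons, although single members changed. The counts that follow are for decitabine against DMSO, and the adjusted p ranges cover all 5 comparisons. Of 17 genes of the DNA methylation machinery 1 rose and 7 fell (the same adjusted over the list alone, 0.088 to 0.35), among them DNMT1, its partner UHRF1 (-0.61 ± 0.13) and the helicase HELLS (-0.95 ± 0.15). Nuclear receptors and steroid enzymes rose in 9 and fell in 3 of 22 (11 and 4 adjusted over the list alone, 0.054 to 0.9), with the steroid enzyme HSD3B1 at 2.38 ± 0.44, and against LNCaP the list passed without LNCaP replicate 2 (0.037) or 3 (0.033). Of 10 neuroendocrine genes 5 rose and 2 fell (0.11 to 0.86), with the neuronal hydrolase UCHL1 at 5.65 ± 0.74. Of 11 mesenchymal genes 5 rose (0.23 to 0.86), with TGFBI at 4.32 ± 0.46. Of 20 luminal epithelial genes 8 rose and 4 fell (0.23 to 0.69). Of 11 basal epithelial genes 6 rose (0.065 to 0.82), with the laminin subunit LAMB3 at 3.6 ± 0.22, and the list passed without DMSO replicate 1 (0.049) or decitabine replicate 3 (0.034). Of 18 Wnt pathway genes 7 rose and 5 fell (0.056 to 0.68), with the feedback inhibitor AXIN2 at 1.6 ± 0.16. Genes of decitabine uptake and metabolism fell in 5 of 8 (0.08 to 0.67), with the nucleoside transporter SLC29A1 at -0.96 ± 0.12 and the activating kinase DCK at -0.59 ± 0.13. Of 11 imprinted genes 4 rose and 2 fell (0.12 to 0.83), and of 3 endogenous retroviral genes 2 rose (0.23 to 0.99). These counts for neuroendocrine to endogenous retroviral genes were the same adjusted over the list alone. Of 4 fibroblast markers 1 rose (0.31 to 0.81), of 4 endothelial markers 1 rose and 1 fell (0.37 to 0.81), and of 4 markers of HeLa and other carcinoma lines 1 rose (0.22 to 0.73). Of 9 immediate early genes 4 rose (0.12 to 0.88), with IER3 at 4.44 ± 0.37 (11.4 against 0.512 CPM), and the list passed with the combination without combination replicate 3 (0.034). Of 11 unpolyadenylated histone genes 7 rose and 1 fell (0.051 to 0.55), with H4C8 at 2.5 ± 0.55, and the list passed without DMSO replicate 1 (0.04) or 2 (0.039) or decitabine replicate 3 (0.022). No list in any comparison passed with an estimated correlation, the lowest adjusted p being 0.053. The median, mean and test of a list differed in sign in 17 of the 135 list tests, none of them among the 30 that passed. The medians of those 30 were the same, at 2 decimals, with genes at 0 reads set at their bound.

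**Figure D4:**
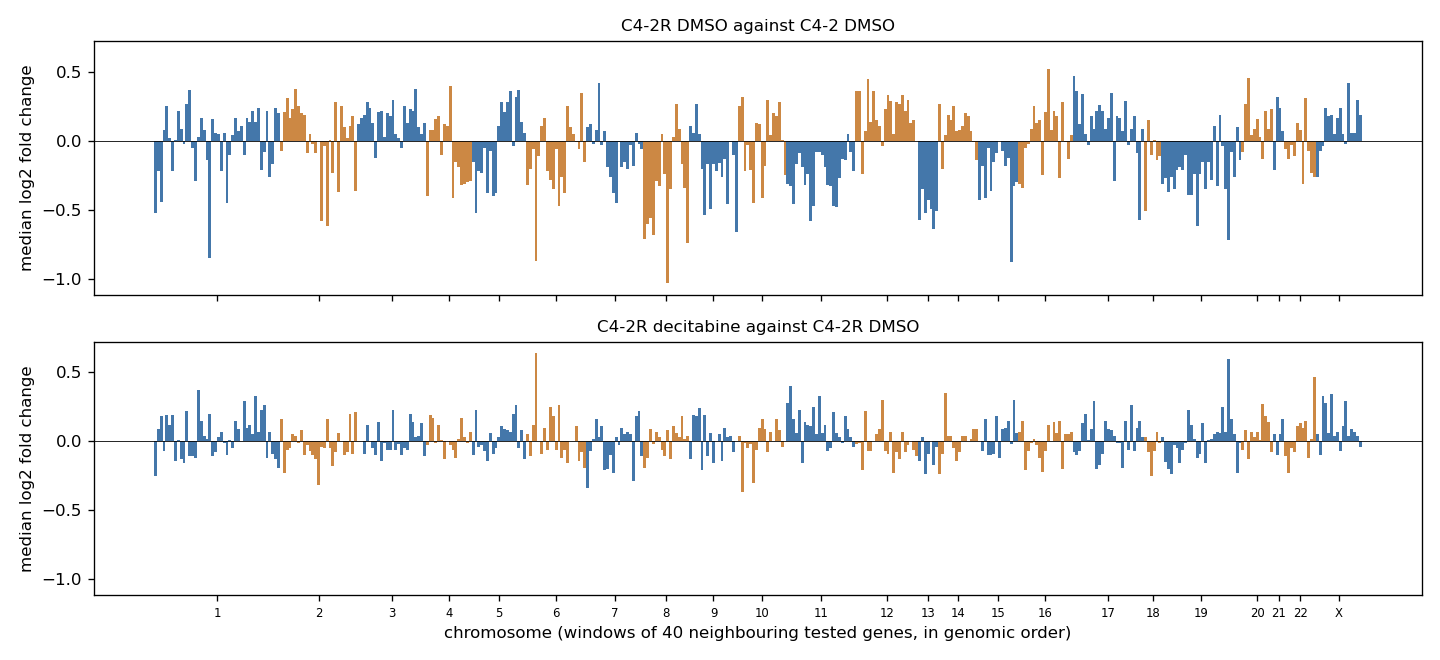
Median log2 fold change in windows of 40 neighbouring tested genes along the chromosomes, for C4-2R against C4-2 (top) and decitabine against DMSO (bottom), with colours alternating by chromosome. Neighbouring genes differ between the lines in blocks, such as the window at -1.03 on chromosome 8.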

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

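The setting that leaves out replicate 3 of both treated groups together, and the one that leaves out replicate 2 of LNCaP and C4-2 together, were tests chosen after the data were seen. No result that passed in either fit turned its direction in any setting run, while values near 0 that had not passed did, such as DNMT3B with decitabine (-0.25 to 0.13). Of the values of named genes, 578 of 578 kept their side of the threshold with RLE scaling, 569 of 577 with DESeq2, 564 of 578 with limma-voom, 555 without the filter, 529 of 537 with only the 6 libraries compared, 575 with the replicate block, none of the changes between the combination and decitabine, and 3205 of 3468 on leaving out single libraries. The 16 counts of genes stayed within 1.5 times with RLE, DESeq2, limma-voom and the stricter filter, and the 4 counts of the line comparisons did so without replicate 2 of LNCaP and C4-2. Of the 135 list tests 134 were as before with RLE, 123 without the filter and 128 with the replicate block, and 765 of 810 on leaving out single libraries.

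Counts moved by more than 1.5 times mostly where the threshold itself was stricter. Against a minimum log2 fold change of 0.5 (glmTreat), genes higher and lower were 2364 and 2849 for C4-2R against LNCaP, 1919 and 3218 against C4-2, 2292 and 762 with decitabine, 2814 and 868 with the combination, and 151 and 253 between the treatments. Reversed genes, raised and lowered, were then 388 and 121 for decitabine and 437 and 91 for the combination, and 1998 and 437 genes were shared by both treatments. With at least 2-fold in every comparison they were 499 and 61 for decitabine, 531 and 47 for the combination, and 2190 and 233 shared. At an adjusted p under 0.01, the combination against decitabine gave 329 higher and 471 lower, reversal gave 572 and 793 for decitabine and 580 and 740 for the combination, and 1798 lowered genes were shared. With resistance defined by C4-2 alone, decitabine raised 1574 genes and the combination 1577. The fit on only the 6 libraries gave 1396 genes lower with the combination than with decitabine, where the cause was not tested.

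Without the filter 11 lists passed for decitabine, and with the replicate block 7 passed for the combination against decitabine, and in both the cause was not tested. The block also added immune checkpoint and chemokine genes for C4-2R against C4-2 (0.048), and antigen presentation (0.049), basal epithelial (0.042) and unpolyadenylated histone genes (0.047) for decitabine, where 10 lists then passed in place of 7. The lists called at the preset correlation of 0.01 had higher estimated ones, from 0.07 (immune checkpoint and chemokine genes against LNCaP) to 0.89 (mitochondrial transcripts). A higher correlation raises p, though how much of the change in calls it explains was not tested. With an estimated correlation camera called 0 lists in each of the 5 comparisons. At an unadjusted p under 0.05 it had 3, 1, 2, 1 and 2 lists, in the order of the report, and fry, which does not compare a list with other genes, called 19, 17, 20, 24 and 6. Leaving out single libraries gave 305 to 610 genes higher with the combination than with decitabine and 2 to 10 lists. Without replicate 3 of both treated groups 375 were higher, with fewer samples in the fit. For a tested gene with 0 reads in a group, depth sets a floor of 0.0432 to 0.0477 CPM, which bounds nothing for genes listed at 0 in all 15 libraries.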

Other observations

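The tests of gene families, of sequencing depth for the replicate 3 libraries, of genes at 0 reads within families used by every cell, and of silent and of X-linked genes among those that pass the filter in LNCaP and C4-2 were chosen after results were seen. Small calcium-binding proteins of the S100A family rose together with treatment. S100A2, S100A4 and S100A6, and the metallothionein MT1G below, are also members of lists of the report, so these families overlap with them. With decitabine 8 of 9 tested S100A genes rose (median 1.62, adjusted p = 0.00035, adjusted p = 0.22 with an estimated correlation), and with the combination 8 of 9 (median 2.23, adjusted p = 0.00015, adjusted p = 0.15 with an estimated correlation). S100A16, named after its values were seen, rose by 5.9 ± 0.29 with decitabine (12.3 against 0.203 CPM) and by 6.65 ± 0.29 with the combination. S100A14, chosen in the same way, rose by 5.24 ± 0.33 and 7.11 ± 0.33. Of 7 metallothioneins, which bind zinc and copper, 5 rose with decitabine (adjusted p = 0.011, adjusted p = 0.15 with an estimated correlation), with MT1E at least 148-fold higher and MT1G at a ratio of 680 (122 to 26900). With the combination 5 rose and 1 fell (adjusted p = 0.017, adjusted p = 0.15 with an estimated correlation). MT2A, also chosen after its values were seen, had log2 fold changes of -0.53 ± 0.27 with decitabine (adjusted p = 0.134) and -0.86 ± 0.27 with the combination (adjusted p = 0.0197).

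Between the lines, all 18 tested Y-linked genes were lower in C4-2R than in LNCaP (median -8.55, adjusted p = 3e-11, adjusted p = 0.055 with an estimated correlation), and of 411 zinc finger genes named ZNF 199 were lower and 58 higher (adjusted p = 0.00035, adjusted p = 0.55 with an estimated correlation). Of 3 clustered protocadherins 3 were lower (adjusted p = 0.026, adjusted p = 0.22 with an estimated correlation). Against C4-2 these families did not pass. There 4 Y-linked genes were lower and 0 higher (adjusted p = 0.19). For zinc finger genes 110 were higher and 113 lower, and for protocadherins 1 was higher and 0 lower (0.97 each). Cytosolic ribosomal protein genes did not pass against LNCaP, with 17 higher and 18 lower (0.97). Of 75 cytosolic ribosomal protein genes 36 were higher and 1 lower in C4-2R than in C4-2 (adjusted p = 0.00035, adjusted p = 0.84 with an estimated correlation), and with decitabine 31 were lower and 4 higher (adjusted p = 3.2e-05, adjusted p = 0.8 with an estimated correlation), where RLE scaling gave 25 lower. With the combination 10 were lower and 4 higher and the family did not pass (adjusted p = 0.068). Against decitabine the combination had the family higher (median 0.14, adjusted p = 0.00035, 0.00024 with the replicate block, and adjusted p = 0.84 with an estimated correlation), although 0 of its genes were called higher and 1 lower. Of 15 HOX genes 4 were higher with the combination than with decitabine (adjusted p = 0.014, adjusted p = 0.31 with an estimated correlation), and 5 with the replicate block (0.0037, and 0.15 with an estimated correlation). RLE scaling gave the same directions for the families named here.

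Replicate 3 of both treated groups lay nearer to C4-2R DMSO than replicates 1 and 2. Untreated RNA mixed evenly into these libraries would lower induced and raise reduced genes by 1 fraction, but for decitabine the fraction was 0.416 ± 0.02 (SE) from 137 induced genes and 0.212 ± 0.013 from 314 reduced genes, a difference of 0.204 ± 0.024. For the combination it was 0.444 ± 0.023 from 109 genes and 0.188 ± 0.01 from 346, a difference of 0.256 ± 0.025, so even mixing is argued against in both. These SE come from drawing the genes of a library again, which are not independent replicates, and leave out the spread between libraries. Both cases also use the same DMSO libraries. Depth is argued against as well, since 0 of the 2 replicate 3 totals lay below both other totals of their group. A weaker or slower response of those cultures, or a day or handling step shared by replicate 3, may remain, and neither was tested.

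Differences between C4-2R and C4-2 ran in blocks along the chromosomes. The SD of medians over 422 windows of 40 neighbouring genes was 0.268, above the highest of 100 shuffled orders (0.171), so chance order is argued against. Windows stood at -1.03 on chromosome 8 (74321130–86321146), -0.87 on chromosome 6 (25279078–27256624), where histone genes lie, and 0.52 on chromosome 16 (30923055–33707213). Copy number that differs between the lines may be a source, since the excess variance with decitabine, within 1 line, was 0.166 of that between the lines (95% interval 0.099 to 0.24), though any stable regional difference between lines would give the same. The window on chromosome 6 also moved within C4-2R, by 0.64 with decitabine and 0.5 with the combination, which a copy number difference alone does not give. Unpolyadenylated histone genes, a sign of RNA quality, went the same way without passing as a list. Of 11, 9 were lower and 1 higher than in C4-2 (median -0.99, adjusted p = 0.12), and 7 were higher and 1 lower with decitabine (median 1.17, adjusted p = 0.051), so RNA quality or its capture may lie behind this window, which was not tested. Regional silencing that decitabine lifts was predicted to give a clearly negative correlation of window medians. The correlation was -0.08 (-0.19 to 0.041, across windows, which are not independent replicates), and the whole interval lies above the value set beforehand. This argues against silencing of that extent over the windows as a set. A weaker form stays open, because the interval spans the bound set for its absence. Both contrasts use the same DMSO libraries, and 20 simulations without a treatment effect gave a correlation of -0.04 ± 0.06 (SD), which spans the observed one. The covariance, -0.00295, lay beyond that of the simulations (-0.000327 ± 0.00049). Those had no treatment effect, so their spread leaves out the scatter that real effects of decitabine add, and this cannot decide. The interval of the correlation over windows includes 0, and neither value settles whether a weaker form exists.

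Several genes common to most cells were listed at 0 in all 15 libraries, among them RPS4X, TUBA1B, MDH1, CDK2, JUNB, TAP1 and IRF1, chosen after their values were seen. Within the annotation used for positions, loss of reads only where genes overlap on the same strand is argued against. There 17 of 24 protein-coding genes covered on the opposite strand alone were at 0 (70.8%), 6.22 times the share of uncovered genes. Loss of reads under exons of any other gene could be a part of it, with 27.5% of 505 covered genes at 0 against 11.4% of 15885 uncovered ones, a ratio of 2.42, but the value lies between the bounds set for it. In families used by every cell the ratio was 5.4, from 2 of 7 covered and 10 of 189 uncovered genes (Fisher's exact test, two-sided, p = 0.061), too few to decide. RPS4X had no covered exon, and the other genes named above had 0.0383 (MDH1) to 0.3663 (TUBA1B) of their exonic bases covered. Most of their exonic bases were uncovered in the annotation used for positions. That annotation lacked some of the counted identifiers, and the one behind the counts was not stated. A gene uncovered in the former may be covered in the latter, so these values cannot decide whether cover accounts for these zeros. The shares of covered genes above have the same limit. No biological explanation was tested, and it remains that such zeros, those in the interferon and antigen presentation lists included, cannot be read as silence.

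One hypothesis was that genes raised by decitabine lie on the X chromosome, where many cancer-testis genes are, more often than elsewhere. Another was that they start from silence. Over all tested genes the odds ratios, 1.48 and 4.69, say nothing, because the filter keeps genes silent in C4-2R DMSO only if they are expressed in another group. Among genes that pass the filter in LNCaP and C4-2 alone, 22.5% of 533 X-linked genes rose against 19% of others (odds ratio 1.24, 95% interval 1 to 1.53, Fisher's exact test, two-sided, p = 0.043). This is at the edge of the threshold, and X-linked genes as a set did not pass the list test (adjusted p = 0.17). For silence the odds ratio among the same genes was 1.96 (1.74 to 2.2, 29.6% of 1665 silent genes against 17.7% of others), which may reflect that a silent gene can only be called raised.

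For each of the 5 comparisons 1 of the 10 splits of its 6 libraries, the real one, gave as many genes as the real split, with 10080, 10280, 7851, 8496 and 1512 genes in the order of the report and 0 as the highest other, and 10 splits are too few for a share under 0.05. Replicate 2 of LNCaP and of C4-2 stood above the other 2 replicates of its group for a few genes induced by low oxygen, chosen after their values were seen. ENO2 was higher by 3.24 and 1.68 (log2), PFKFB4 by 3.29 and 1.55, VEGFA by 2.4 and 1.27 and BNIP3 by 1.85 and 0.74. No list of genes induced by low oxygen was tested.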
